A study of Mus musculus with 2 samples.

How the data were processed

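Kidney glomerular cells of 2 mice were profiled by droplet-based single-cell RNA sequencing, with 1 library from the mouse titled female and 1 from the mouse titled male. Per the labels' protocols, the suspension had 95% viability and 10x 3' libraries were sequenced on a NextSeq500. Cell Ranger 6.1.2, STAR 2.7.5a and the mouse genome build mm10 were used, per the submitters' processing notes, which do not give the role of each tool. The filter by which barcodes were called cells, the gene annotation and the strand used in counting are not given in the sources used here. The deposited values are raw counts, whole numbers of UMIs per gene and barcode with no normalization, per the file headers and the values themselves. The feature list holds 31058 entries, of which 31053 carry Ensembl gene identifiers and 5 are reporter sequences (hrGFPIINLS, EYFP, tdimer2, MbmCerulean and EGFP). Symbols carried by more than 1 identifier, 35 entries in all, were kept apart by identifier. Coordinates come from the GENCODE M21 annotation of GRCm38, the assembly also called mm10, in which 31011 of the identifiers were found. They span whole genes, and the counts do not separate exons from introns.

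Groups follow the sample titles. The file names carry the opposite sex, and so the level of Xist and of 4 Y-linked genes was computed in each library before any direction was drawn. Barcodes with over 20% mitochondrial UMIs (283 in the library labelled female, 504 in the library labelled male) or under 500 genes (112 and 145) were left out. Scrublet, as in scanpy 1.11.5, was run per library with an expected doublet share of 4%; it called 3 and 1 cells, under 0.5% of the cells, and so it has not worked here. Mixed cells therefore remain, and alternatives without the 5% of cells with the highest Scrublet scores were added after seeing the data. The 9347 kept cells were scaled to 10000 UMIs, log transformed and reduced to 30 principal components of 2000 variable genes, without mitochondrial, reporter, Xist and Y-linked genes. Leiden clustering (leidenalg 0.10.2, python-igraph 0.11.9, resolution 1.0) ran on a shared-neighbour graph over 20 nearest neighbours (scikit-learn 1.9.0) and gave 19 clusters.

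Clusters were called X-like from 19 marker lists. A marker counted for a cluster when it was in over 20% of its cells, at 50 CPM or more and over 2-fold above the lower quartile of the clusters, and a name needed 3 or more such markers. The highest mean relative level of the markers gave the name, haemoglobin genes gave one only where they held over 20% of the UMIs, and a cluster stayed unnamed where its top 10 genes held more markers of another type than of its own, or 3 or more cell cycle genes and none of its own markers. This naming rule was set after the clusters were seen. It left 3 clusters unnamed, each with podocyte markers, and an alternative that names clusters by the marker score alone was added after seeing the data.

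Raw counts were summed per library and class, for the 6 classes with at least 50 cells in each library, and expressed as CPM of the class sum. Ratios were taken as log2 of CPM plus 10, the library labelled female over the library labelled male. This prior pulls the ratio of low genes towards 0, while printed folds are ratios of CPM without it. Each group had 1 library, so no test between groups was possible. Sums have exact Poisson intervals, ratios exact conditional binomial intervals and shares exact Clopper-Pearson intervals, all at 95% and covering counting error only. A count of 0 was read as allowing up to 3 counts. The precision followed the depth, with 3664 and 3335 podocyte-like cells at medians of 11040 and 9960 UMIs, but 111 and 87 glomerular endothelial-like cells at medians of 7960 and 6452 UMIs.

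For 27 gene lists, 2 of which hold the X inactivation transcript and the Y-linked genes, the median log2 ratio was taken over members at 20 CPM or more in either library. Its interval came from 200 Poisson redraws of the counts. Its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, describes these libraries and is no test. Cells in G2 or M phase were counted as those with at least 2 UMIs of the phase genes after each cell was thinned to 3000 UMIs. All kept cells were deeper than that. Counts were also simulated as independent Poisson draws from the summed profile, with 200 genes changed. Over 3405 genes the ratio intervals held the true value for 95.3% at the full UMI totals and 96.1% at 1% of them. The intervals assume this same model, so the simulation does not cover UMIs that clump in few cells.

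Genes were named by a rule of size: at 50 CPM and 30 UMIs or more in the higher library, at 20% or more of the level in the class with the highest level there, leaving out mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and unnamed predicted genes. The 8 highest and 8 lowest ratios were taken in podocyte-like cells, 5 and 5 in the other glomerular classes and 3 and 3 elsewhere. From each list up to 4 members could be named, those farthest from 0 and those at the highest level, besides sex-linked genes, steroid receptors and class markers. Some genes that this rule names are not reported here. The groups, the lists, the marker genes, the rule for named genes, the filters and a set of alternative settings were chosen before the data were examined. These alternative settings changed the mitochondrial limit, the gene minimum, doublet removal, clustering resolution, scaling within libraries, scaling of the sums (TMM factors of edgeR 4.0.16 in R 4.3.3, or totals without mitochondrial and ribosomal protein genes), thinning, the prior and the level minimum of list members. The reporter sequences were analysed only after the feature list had been seen, and 5 further gene lists were added after the ratios had been seen. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.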

Results

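Single-cell RNA sequencing was carried out on kidney glomerular cells of 2 healthy mice on the C57Bl/6 background, 1 titled female and 1 titled male. The mice carried Pax2.rtTA, TetO.Cre and R26.Confetti, a doxycycline-inducible system in which cells that express Pax2 recombine a cassette and keep 1 of several fluorescent reporters. Doxycycline was given at 19 days of age and the mice were killed at 30 days. Each mouse gave 1 library of 10x 3' transcript counts, so each group had 1 library and no difference between the groups has a replicate check. The library labelled female held 5233 barcodes and 67648465 UMIs (unique molecular identifiers, each standing for 1 captured transcript), with a median of 10750 UMIs and 3463 genes per barcode. The library labelled male held 4974 barcodes and 57841860 UMIs, with medians of 9770 UMIs and 3262 genes. After filtering, 4906 cells with a median of 10670 UMIs and 4441 cells with a median of 9612 UMIs remained. Intervals in brackets are 95% intervals and cover counting error only, not differences between animals.

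The first comparison asked whether sex-linked transcripts followed the titles, and in both libraries they were opposite to them. Xist, the non-coding RNA of the inactive X chromosome (X:103460366 to 103483254, minus strand, GRCm38), was at 0.682 CPM (counts scaled to the total UMIs of the library or class; 0.492 to 0.923) in the library labelled female and at 1590 CPM (1580 to 1600) in the library labelled male. It was seen in 28 of 4906 cells (0.571%) of the former and in 4418 of 4441 cells (99.5%) of the latter. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d together reached 214 CPM (210 to 218) in the library labelled female, where 84.2% of cells (83.2 to 85.3%) held at least 1 of their UMIs. The library labelled male held 1 UMI of Kdm5d and none of the other Y-linked genes, in 4441 cells. Ddx3y, an RNA helicase gene of the Y chromosome (Y:1260771 to 1286629, minus strand), was at 132 CPM in the library labelled female, and 0 UMIs in the other library allow up to 0.0617 CPM.

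The X-linked partners of these genes, which escape X inactivation in part, were lower in the library labelled female. Ddx3x was at 245 and 371 CPM in the libraries labelled female and male, Kdm6a at 50.4 and 89.3 CPM, Eif2s3x at 37.2 and 65.2 CPM, and Kdm5c at 36.0 and 46.1 CPM. Tsix, which overlaps Xist on the opposite strand, was at 2.52 and 140 CPM. Its level is uncertain, because the strand used in counting is not given in the sources used here and Tsix and Xist reads cannot then be separated. The names of the deposited files carry the sex opposite to the sample titles. Groups below keep the titles, and every ratio is the library labelled female, which was Y-positive, over the library labelled male, which was Xist-positive.

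**Figure D1:**
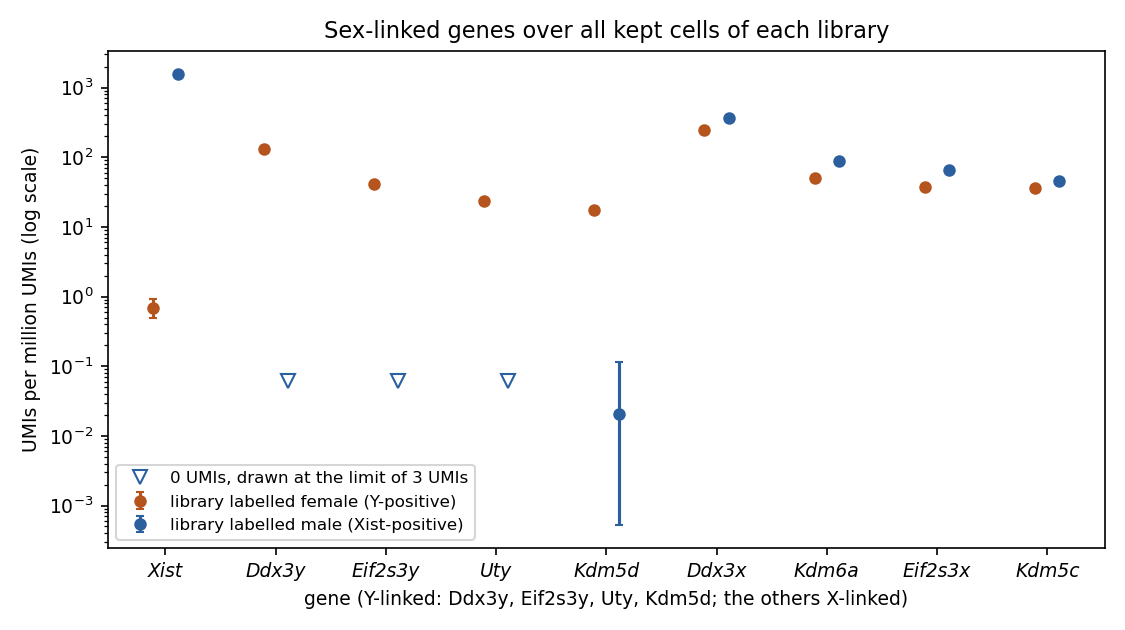
CPM on a log axis of Xist, the Y-linked genes and their X-linked partners in the kept cells of each library, with lines for exact 95% Poisson intervals and open triangles, drawn at the limit of 3 UMIs, for genes with 0 UMIs. Xist stands at 0.682 CPM in the library labelled female and at 1590 CPM in the library labelled male, and Ddx3y at 132 CPM and 0 UMIs.

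The second comparison asked how the cells of each library were divided among cell types. Podocyte-like cells, which carried Nphs1, Podxl and other podocyte markers, made up 74.7% (73.4 to 75.9%; 3664 cells) of the library labelled female and 75.1% (73.8 to 76.4%; 3335 cells) of the library labelled male. Mesangial-like cells made up 4.87% (4.29 to 5.51%) and 3.92% (3.37 to 4.53%), parietal epithelial-like cells 2.38% (1.98 to 2.85%; 117 cells) and 1.69% (1.33 to 2.11%; 75 cells), and glomerular endothelial-like cells 2.26% (1.86 to 2.72%) and 1.96% (1.57 to 2.41%). Among these 4 glomerular classes alone, podocyte-like cells made up 88.7% (87.7 to 89.6%) and 90.8% (89.9 to 91.8%). T or NK-like cells were fewer in the library labelled female, at 0.163% (0.0704 to 0.321%; 8 cells) against 0.721% (0.493 to 1.02%; 32 cells). Macrophage or monocyte-like cells stood at 0.245% and 0.585%, smooth muscle or renin-like cells at 0.897% and 1.40%, arterial endothelial-like cells at 1.71% and 1.91%, and thick ascending limb-like cells at 1.12% and 1.67%. Proximal tubule-like cells stood at 0.204% and 0.495% and distal convoluted tubule-like cells at 0.143% and 0.450%.

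Clusters without a name held 11.3% and 10.1% of the cells. The largest of them was led by haemoglobin genes at 8.44% and 7.32%, another by Cst12, Igfbp6 and Dkk3 at 2.41% and 2.54%, and a small one by cell cycle genes at 0.469% and 0.248%. In the largest, haemoglobin genes held only 0.853% of the UMIs, and 10 podocyte markers counted for it. The podocyte-like shares above do not include the cells of these clusters. With clusters named by marker score alone, an alternative chosen after seeing the data, podocyte-like cells made up 85.5% and 85.0%. The parietal epithelial-like shares were 4.65% and 4.01% at a coarser clustering and 1.49% and 1.13% with a mitochondrial limit of 50%, and the glomerular endothelial-like shares were 3.97% and 3.87% at the coarser clustering, which left no arterial endothelial-like class.

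**Figure D2:**
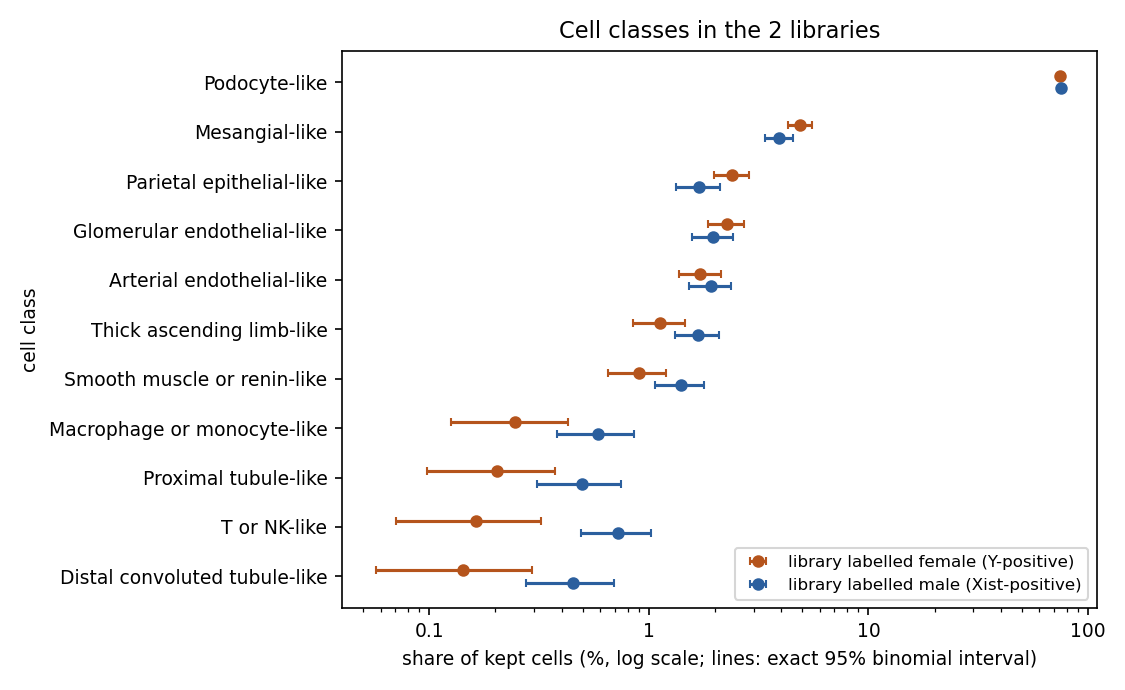
Share of kept cells in each X-like class, in percent on a log axis, for the libraries labelled female and male, with lines for exact 95% Clopper-Pearson intervals. Podocyte-like cells stand at 74.7% and 75.1%, and T or NK-like cells at 0.163% and 0.721%.

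Cells in G2 or M phase were counted in both libraries. With each cell thinned to 3000 UMIs, 53 of 4906 cells (1.08%; 0.810 to 1.41%) of the library labelled female and 36 of 4441 cells (0.811%; 0.568 to 1.12%) of the library labelled male held at least 2 UMIs of the G2 and M phase genes. Without thinning the shares were 3.75% and 2.93%. Among podocyte-like cells the thinned shares were 0.136% and 0.150%, among mesangial-like cells 3.35% (8 cells) and 1.72% (3 cells), and among parietal epithelial-like cells 2.56% (3 cells) and 5.33% (4 cells). Without thinning the parietal epithelial-like shares were 34.2% (25.7 to 43.5%) and 22.7% (13.8 to 33.8%), which turns their direction, and the podocyte-like shares 1.64% and 1.68%. In each of these classes the intervals of both libraries overlapped, and free RNA of cycling cells stays open as a source of the UMIs.

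The third comparison asked which transcripts differed between the podocyte-like cells of both libraries. Immediate early and stress genes were higher in the library labelled female: all 17 measured genes of this group had a ratio above 1, and 10 of them were at least 1.5-fold higher. Their median log2 ratio was 0.62 (0.61 to 0.64), above the median of each of 10000 random lists matched on expression. Fos and Jun, which encode the subunits of the AP-1 transcription factor, stood at 4405 against 3078 CPM and at 6726 against 4582 CPM. Atf3, a stress-induced transcription factor gene (1:191170296 to 191218039), stood at 1646 against 807 CPM, 2.04-fold higher (2.01 to 2.07). Hspa1b, an inducible heat shock protein gene, stood at 323 against 129 CPM, a value that is uncertain because its near-identical paralog Hspa1a can share its reads.

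Nfkbia, Cebpd and Ifrd1 were also among the genes with the highest ratios in podocyte-like cells. Nfkbia, which encodes an inhibitor of NF-kappaB, stood at 1014 against 494 CPM (2.05-fold; 2.02 to 2.09), Cebpd at 111 against 49.2 CPM (2.25-fold; 2.13 to 2.38) and Ifrd1 at 457 against 222 CPM (2.06-fold). Nfkbia and Atf3 had this direction in 6 of 6 podocyte-like clusters, Cebpd and Ifrd1 in 4. In the library labelled female most podocyte-like cells lay in clusters 0 and 1, and in the library labelled male in clusters 0 and 2. Within the 6 podocyte-like clusters the median log2 ratio of the stress genes ran from -0.06 to 0.22. Cluster 1 was led by immediate early genes. It held 28.6% of the podocyte-like cells of the library labelled female and 11.6% of those of the library labelled male. Without that cluster, an alternative chosen after seeing the data, the median log2 ratio of the stress genes was 0.33, and the log2 ratios of Cebpd, Ifrd1, Atf3 and Nfkbia were 0.12, 0.34, 0.46 and 0.47. The mitochondrial limit was exceeded by 5.41% of the barcodes of the library labelled female and 10.1% of those of the library labelled male.

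**Figure D3:**
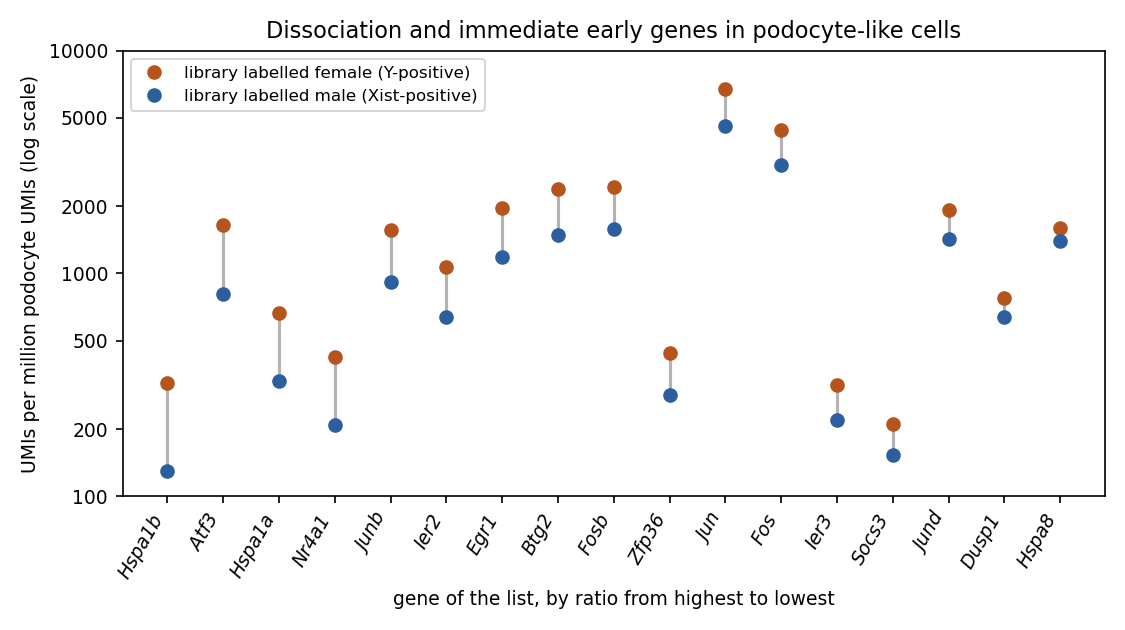
CPM on a log axis of the 17 immediate early and stress genes in the podocyte-like cells of the libraries labelled female and male. Each of the 17 genes is higher in the library labelled female, with Jun at 6726 and 4582 CPM and Atf3 at 1646 and 807 CPM.

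Outside this group, the highest ratio of an autosomal gene that met the rule for named genes in podocyte-like cells was that of Nell2, which encodes a secreted glycoprotein with EGF-like repeats (15:95075230 to 95528559), at 157 against 41.2 CPM (3.81-fold; 3.60 to 4.03). Ucp2, which encodes a mitochondrial inner membrane carrier, stood at 275 against 117 CPM (2.36-fold; 2.28 to 2.44). Higher in the library labelled male were Thsd7a (6:12311610 to 12749410), which encodes a podocyte membrane protein targeted by autoantibodies in membranous nephropathy, at 1488 against 2502 CPM (1.68-fold; 1.67 to 1.70), and Scd2, a stearoyl-CoA desaturase gene, at 291 against 439 CPM (1.51-fold; 1.48 to 1.54). AY036118 stood at 1869 against 3904 CPM, a value that is uncertain because this transcript resembles ribosomal RNA. Nell2, Ucp2, Thsd7a, Scd2 and AY036118 each had the same direction in all 6 podocyte-like clusters. Thsd7a was among the top 10 genes of cluster 2. That cluster held 10.4% of the podocyte-like cells of the library labelled female and 22.2% of those of the library labelled male. How far this mix of clusters enters the fold of Thsd7a was not tested. Over the 3356 genes that met the level limits and exclusions of the rule for named genes in podocyte-like cells, the 5th and 95th percentiles of the log2 ratio were -0.20 and 0.20.

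Genes of podocyte structure were at nearly equal levels in both libraries. None of the 18 measured slit diaphragm and cytoskeleton genes differed by 1.5-fold, and their median log2 ratio was -0.04 (percentile 5.28 of the random lists). Podxl, which encodes podocalyxin, stood at 4253 against 4512 CPM, while the log2 ratios farthest from 0 were those of Actn4 (-0.22) and Inf2 (0.20). The median was 0.01 for 7 podocyte transcription factor genes and 0.07 for 8 glomerular basement membrane genes. The 4 X-linked partners of the Y genes had a median of -0.62, below each of the random lists.

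The fourth comparison concerned parietal epithelial-like cells, the lining of Bowman's capsule, in which Pax2 is active and from which podocyte progenitors have been described. The simple epithelial keratin genes Krt8 and Krt18 were higher in the library labelled female: Krt8 (15:101996698 to 102004482) stood at 299 against 89.0 CPM (3.36-fold; 2.75 to 4.15) and Krt18 at 81.6 against 36.9 CPM (2.21-fold; 1.60 to 3.12). Prom1, which encodes the progenitor marker CD133, stood at 28.8 against 15.2 CPM (1.89-fold; 1.12 to 3.33) and Akap12, a scaffold protein gene at a high level in this class, at 2208 against 2417 CPM. Of the 11 measured parietal epithelial and progenitor genes 8 had a ratio above 1, and their median log2 ratio was 0.13 (percentile 96.9). Over the alternatives this median ranged from 0.04 to 0.49, and the log2 ratio of Krt8, 1.64, was 0.83 with a mitochondrial limit of 10%.

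Also higher in parietal epithelial-like cells of the library labelled female were Sult1d1, a sulfotransferase gene, at 199 against 84.2 CPM (2.37-fold; log2 ratio 1.15, and 0.44 after thinning), Dbp, a circadian transcription factor gene, at 97.1 against 39.3 CPM (2.47-fold), and Pmepa1, a TGF-beta target gene, at 91.5 against 36.9 CPM (2.48-fold). Pycard, which encodes an inflammasome adaptor, was higher in the library labelled male, at 40.8 against 88.2 CPM (2.16-fold; 1.63 to 2.88), as was Eif4enif1 at 25.3 against 52.9 CPM (2.09-fold). Steroid hormone receptor genes were at similar levels in this class, with Pgr at 39.5 against 43.3 CPM and Nr3c1 at 146 against 148 CPM. The 17 measured estrogen response genes had a median log2 ratio of 0.05 (percentile 75.1). Mesangial matrix and contraction genes had a median of -0.23 (percentile 0.07) in this class, which was -0.04 at a coarser clustering. The 4 measured G2 and M phase genes had a median of 0.99, which was 0.25 after thinning, and the 6 podocyte transcription factor genes 0.26 (percentile 99.5), which turned to -0.14 at a coarser clustering.

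The fifth comparison concerned glomerular endothelial-like cells, 111 in the library labelled female and 87 in the library labelled male. Cyp26b1, which encodes an enzyme that degrades retinoic acid (6:84571414 to 84593908), was lower in the library labelled female, at 329 against 1270 CPM (3.86-fold; 3.45 to 4.34). Rarb, a retinoic acid receptor gene that retinoic acid induces, stood at 18.3 against 54.6 CPM, Tgm2, a transglutaminase gene that retinoic acid induces, at 31.4 against 89.1 CPM, and Rarres2, which encodes chemerin, at 42.4 CPM against 0 UMIs. The 9 measured retinoid genes had ratios on both sides of 1 and a median log2 ratio of -0.15 (percentile 10.3), which was -0.42 after thinning, -0.30 without the 5% of cells with the highest doublet scores and 0.06 at a coarser clustering. Esm1, which encodes an endothelial proteoglycan, stood at 4.38 against 57.5 CPM (13.1-fold lower; 5.52 to 37.8), and Mrrf, a mitochondrial translation gene, at 14.6 against 51.7 CPM.

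Antigen presentation genes were lower in the glomerular endothelial-like cells of the library labelled female. All 9 MHC class I genes had a ratio below 1, with a median log2 ratio of -0.46 (percentile 0.01). H2-K1 stood at 817 against 1227 CPM and B2m, which encodes the light chain of class I molecules, at 2059 against 2877 CPM. The immediate early and stress genes had a median of -0.22 (percentile 0.11), the angiogenic signalling genes -0.16 (percentile 1.90) and the interferon response genes -0.15 (percentile 2.07). Over the alternatives these medians ranged from -0.48 to -0.26 for MHC class I, from -0.93 to -0.06 for stress, from -0.19 to -0.02 for angiogenic signalling and from -0.46 to -0.13 for interferon genes. The angiogenic median stayed past the 2.5% limit of the random lists under 12 of 18 alternatives and the interferon median under 15. Dbp was higher in the library labelled female, at 121 against 15.8 CPM (7.67-fold; 4.18 to 15.7).

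Mesangial genes were higher in the glomerular endothelial-like cells of the library labelled female, with a median log2 ratio of 1.35 over 10 genes. Pdgfrb, the PDGF receptor gene of mesangial cells, stood at 162 against 4.31 CPM (37.6-fold; 12.7 to 184), Rtn4rl1 at 55.5 against 2.87 CPM (19.3-fold; 5.17 to 162) and S1pr3 at 99.4 CPM against 0 UMIs, at least 23.1-fold higher. At least 2 UMIs of Pdgfrb were held by 5 of the 111 cells and by 0 of the 87 cells. Without those cells, an alternative chosen after seeing the data, the median of the mesangial genes was 0.04 and the log2 ratios of Pdgfrb and Rtn4rl1 turned to -0.52 and -0.36, while S1pr3 had a log2 ratio of 0.14 without the 5% of cells with the highest doublet scores. The median of the 9 measured estrogen response genes in this class was 0.37 (percentile 99.8) and turned to -0.01 without the same cells.

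The sixth comparison concerned mesangial-like cells, 239 in the library labelled female and 174 in the library labelled male. Interferon-stimulated genes were lower in the library labelled female: 11 of 13 had a ratio below 1, 5 of them by at least 1.5-fold, and the median log2 ratio was -0.52, below each of the random lists. Ifit3, an antiviral effector gene, stood at 200 against 368 CPM (1.84-fold lower; 1.63 to 2.07), and Ifit1 at 148 against 244 CPM, while Ifitm3, the member with the highest level, stood at 3804 against 3686 CPM. The 9 MHC class I genes all had a ratio below 1 (median -0.29, percentile 0.24). Cxcl10, an interferon-induced chemokine gene (5:92346638 to 92348889), stood at 15.7 against 66.5 CPM (4.23-fold lower; 2.93 to 6.23), and Casp4, an inflammatory caspase gene, at 21.1 against 67.1 CPM (3.19-fold lower; 2.28 to 4.49). Over the alternatives the interferon median ranged from -0.60 to -0.33 and the MHC class I median from -0.32 to -0.17. The share of T or NK-like cells was 0.163% in the library labelled female and 0.721% in the library labelled male.

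Angptl4 and Ucp2 were higher in the mesangial-like cells of the library labelled female. Angptl4, which encodes an inhibitor of lipoprotein lipase, stood at 210 against 79.5 CPM (2.64-fold; 2.17 to 3.23), and Ucp2 at 195 against 88.8 CPM (2.19-fold; 1.82 to 2.66). Zbtb16, a transcription factor gene that glucocorticoids induce, stood at 131 against 49.7 CPM (2.63-fold). Limch1, an actin-associated protein gene, was lower, at 36.4 against 120 CPM (3.30-fold). Notch signalling genes had a median log2 ratio of -0.47 (percentile 0.09; -0.51 to -0.29 over the alternatives), with Hes1 at 96.5 against 184 CPM.

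Podocyte transcripts were also higher in the mesangial-like cells of the library labelled female. The slit diaphragm and cytoskeleton genes had a median log2 ratio of 0.57 and the podocyte transcription factor genes 0.71, with Nphs1 at 208 against 64.0 CPM (3.26-fold; 2.63 to 4.06). At least 2 UMIs of Nphs1 were held by 30 of 239 cells (12.6%; 8.63 to 17.4%) and 5 of 174 cells (2.87%; 0.939 to 6.58%). Without the cells that carried transcripts of another class, an alternative chosen after seeing the data, the median of the slit diaphragm genes turned to -0.06 and that of the transcription factor genes was 0.03. Mesangial matrix and contraction genes had a median of -0.14 (percentile 2.99; -0.16 to -0.06 over the alternatives).

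Interferon genes were lower in the library labelled female in arterial endothelial-like cells as well, with a median log2 ratio of -0.33 (percentile 0.01; 84 and 85 cells). Cxcl9, a chemokine gene induced by interferon-gamma, had 0 UMIs against 63.0 CPM and was at least 21.3-fold lower. All 7 measured Notch signalling genes had a ratio below 1, with a median of -0.61, below each of the random lists. Notch1, a receptor gene of arterial endothelium, stood at 142 against 240 CPM, its ligand gene Dll4 at 31.6 against 61.9 CPM and its target gene Hes1 at 107 against 178 CPM. Cyp26b1 was lower in this class too, at 70.0 against 330 CPM (4.71-fold; 3.62 to 6.20). The 3 measured steroid hormone receptor genes had a median of -0.70 (percentile 0.05). This median was -0.08 both with no level minimum for members and with members at 100 CPM or more. It stayed below the lower 2.5% limit of the random lists under 9 of 16 alternatives. Higher in the library labelled female were Zbtb16, at 110 against 14.6 CPM (7.55-fold; 4.24 to 14.6), and Fabp5, a fatty acid binding protein gene, at 110 against 20.3 CPM (5.45-fold; 3.30 to 9.53). Over the alternatives the Notch median ranged from -0.77 to -0.31 and the interferon median from -0.35 to -0.17, and the log2 ratio of Fabp5, 1.99, was 0.66 with a mitochondrial limit of 50%.

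In thick ascending limb-like cells (55 and 74 cells) the named genes rested on few cells. Upk3a, a uroplakin gene of the urothelium, stood at 215 against 4.45 CPM, and at least 2 of its UMIs were held by 2 of the 55 cells of the library labelled female. Ly6d and Krt15, at 185 and 130 CPM, had 0 UMIs in the library labelled male. Aqp1, a water channel gene of the proximal tubule and thin limb, stood at 3.83 against 724 CPM, and at least 2 of its UMIs were held by 1 of 55 and 6 of 74 cells. Bst1 had 0 UMIs against 115 CPM. Umod, a marker of this class, had at least 2 UMIs in 42 of 55 and 46 of 74 cells. The class may therefore hold cells of other types, and whether their mix differed between the libraries was not tested. The medians that follow are those of the class as a whole. The immediate early and stress genes had a median log2 ratio of 0.44 in this class, above each of the random lists (0.23 to 0.60 over the alternatives). The 6 measured G2 and M phase genes had a median of 1.52 (0.70 to 1.90 over the alternatives), with at least 2 of their UMIs in 3 of 55 and 1 of 74 cells after thinning. The parietal epithelial and progenitor genes had a median of -0.41 (percentile 0.03; -0.57 to -0.10), the MHC class I genes 0.41 (percentile 98.3; -0.05 to 0.44) and the mesangial genes 0.62, which turned to -0.70 without the 5% of cells with the highest doublet scores.

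Estrogen response genes had medians of 0.10 in podocyte-like cells (percentile 98.0), 0.23 in mesangial-like cells (percentile 99.3), 0.19 in thick ascending limb-like cells (percentile 98.6) and 0.13 in arterial endothelial-like cells (percentile 91.5). The counting intervals of the last pair, -0.02 to 0.29 and -0.04 to 0.24, included 0. Over the alternatives they ranged from 0.01 to 0.12, from 0.18 to 0.24, from 0.01 to 0.52 and from -0.05 to 0.21, and the first 3 stayed past the upper 2.5% limit under 14 of 18, 17 of 18 and 9 of 16 alternatives. Of the kidney genes known to be higher in adult females none was measured in any class, and the 3 measured genes of those higher in adult males had a median of 0.04 in podocyte-like cells. In arterial endothelial-like cells the 4 measured genes of the latter group all had a ratio below 1, with a median of -0.47 (percentile 0.74; -0.95 to -0.26 over the alternatives). The library labelled female was the Y-positive one, so this direction is the reverse of that known from adult males. Mitochondrially encoded genes had a median of 0.16 in mesangial-like, 0.13 in parietal epithelial-like and 0.00 in podocyte-like cells, and nuclear genes of oxidative phosphorylation had 0.16, 0.09 and 0.02; the first of these ranged from 0.08 to 0.20 in mesangial-like and from 0.01 to 0.24 in parietal epithelial-like cells over the alternatives. In podocyte-like cells the MHC class I genes had a median of -0.15 (percentile 1.26; -0.20 to -0.08 over the alternatives), against -0.23 in arterial endothelial-like and -0.08 in parietal epithelial-like cells. Also in podocyte-like cells, the retinoid genes had a median of -0.13, the glycolysis and hypoxia genes 0.05, the Wnt signalling genes -0.09, the renin-angiotensin genes 0.03, the metallothionein and oxidative stress genes 0.05 and the TGF-beta and fibrosis genes 0.20, a median over 3 members that turned to -0.004 without the cluster led by immediate early genes.

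**Figure D4:**
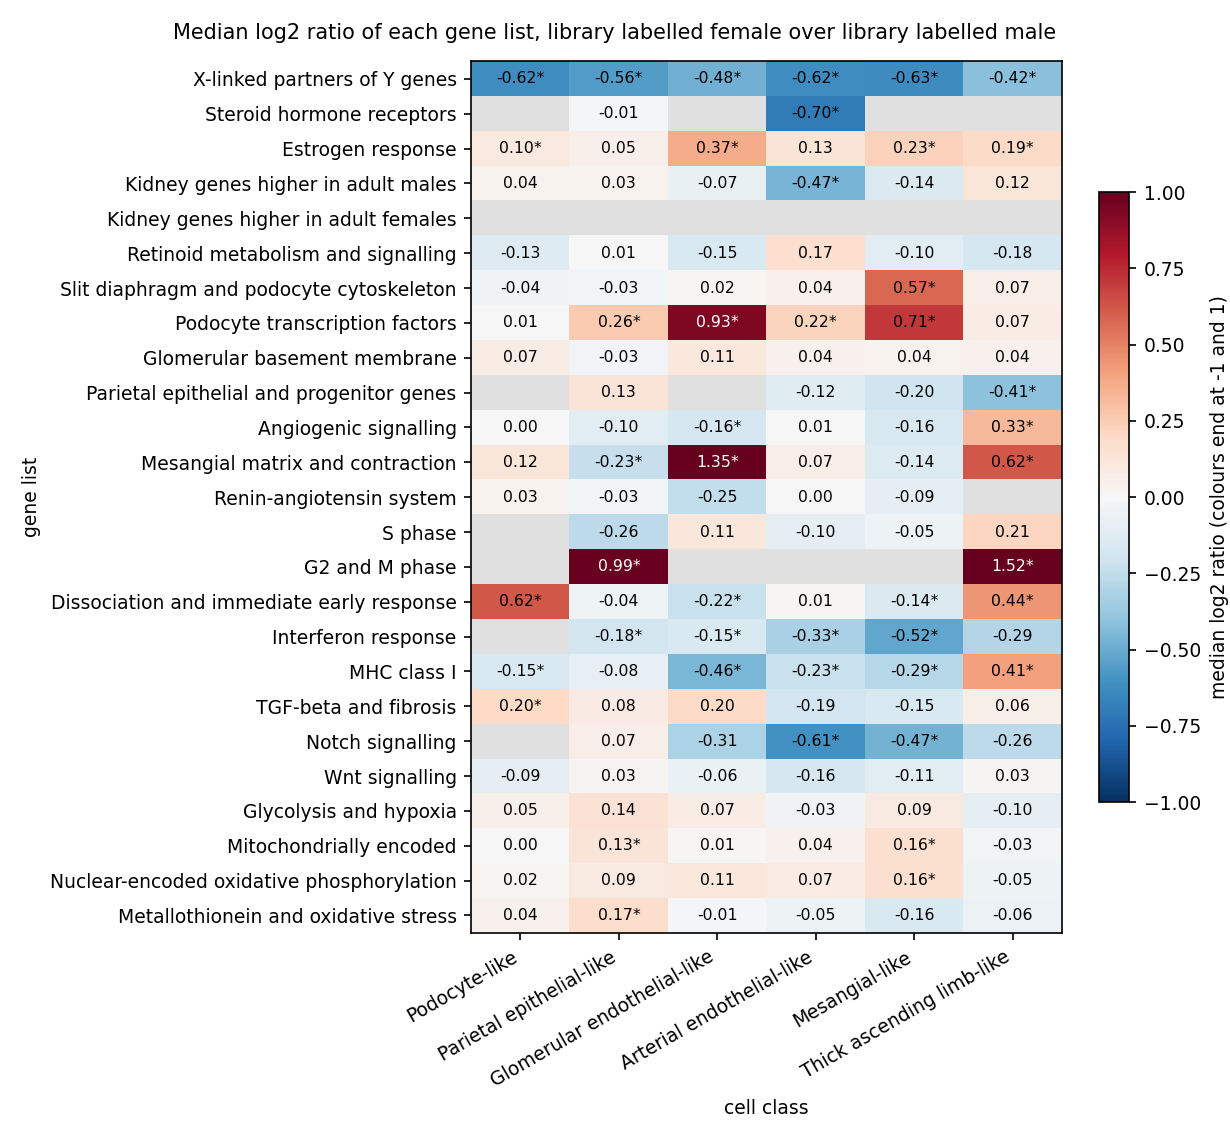
Median log2 ratio, library labelled female over library labelled male, of each gene group in each of the 6 classes with at least 50 cells per library; colours end at -1 and 1, asterisks mark medians in the outer 2.5% at either end of 10000 random lists, and grey marks fewer than 3 measured genes. Stress genes stand at 0.62 in podocyte-like cells, interferon genes at -0.52 in mesangial-like cells and Notch genes at -0.61 in arterial endothelial-like cells.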

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

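In this part the tests of depth and of cluster composition were set out before their results were seen, and the tests of exchanged titles, mixed sexes, free RNA, shared reads, cassette turnover and handling were chosen only after the result was seen.

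MbmCerulean, the membrane-bound cyan reporter of the Confetti cassette, had a UMI in 9.99% (9.04 to 11.0%) of podocyte-like cells of the library labelled female, and EYFP, the yellow reporter, in 1.83% (1.42 to 2.32%). Both were picked out because no comparison above reports a reporter sequence and because their shares differed between the libraries as follows. The shares in the library labelled female lie above the limit that a count of 0 allows there, 0.0819%. In podocyte-like cells of the library labelled male EYFP had 0 UMIs and MbmCerulean was in 0.06%, under the limit there, 0.09%. The intervals of both libraries did not overlap. Such a limit is no background share. In the library labelled female EYFP was, after thinning, in 0.355% (0.189 to 0.606%) of podocyte-like cells and in 0 of 350 mesangial-like and glomerular endothelial-like cells (up to 1.05%). Free RNA therefore stays open for EYFP.

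The sex-linked genes stood opposite to the titles in both libraries. Cells of both sexes mixed within a library are argued against, since the higher share of cells with transcripts of the library's minority sex was 0.571%. An exchange of the titles of both libraries, or of the files under them, is a candidate explanation: 84.2% of cells in the library labelled female had a Y-linked UMI and 99.5% in the library labelled male had Xist. The file names, which carry the sex opposite to the titles, go the same way. However the mismatch arose, the transcripts make every ratio above a Y-positive mouse over an Xist-positive mouse, the reverse of the titles. Sex stays confounded with the single animal, its handling and its library.

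MbmCerulean was in 366 podocyte-like cells of the library labelled female and in 2 (0.0600%) of the library labelled male, although 30.7% of parietal epithelial-like cells of the latter carried it. At 3000 UMIs per cell the podocyte share was 3.11% (2.57 to 3.73%). Mesangial-like and glomerular endothelial-like cells had 0 of 350, with an exact upper limit of 1.05%. The podocyte share was 3.63 times 0.857%, the share that 3 of these 350 cells would give. Free reporter RNA is argued against because the intervals do not overlap. Arterial endothelial-like cells, at 1 of 84 (1.19%; 0.0301 to 6.46%), do not decide it. Depth is argued against because the thinned shares stayed at 3.11% (2.57 to 3.73%) and 0 of 3335 cells, and misassigned hrGFPIINLS reads because cells with both reporters were 0.139 times (0.0599 to 0.273) the number under independence. MbmCerulean and EYFP occurred together 4.03 times (2.66 to 5.87) as often as under independence, and a cassette that recombined again in part of these cells may account for that, but it cannot be told apart from reads shared between the near-identical EYFP and MbmCerulean sequences, and EYFP itself may be free RNA. A difference between both animals in which recombined cells gave rise to podocytes was not tested and stays open.

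Immediate early and stress genes had a median log2 ratio of 0.62 in podocyte-like cells. A single shift of the whole suspension is argued against by the other classes, whose list medians had a median of -0.044 (0.44 in thick ascending limb-like cells and at most 0.01 in each other class), and greater depth by the median of 0.66 after thinning. More cells of the cluster led by immediate early genes, with no difference within clusters, cannot be told apart from a difference within clusters: the medians within the other podocyte-like clusters ran from -0.06 in cluster 2 (6 of 17 genes higher) to 0.22, with a median of 0.12, and that within the cluster led by these genes was 0.19, between no difference and a clear one, and the clusters were themselves drawn in part from these genes. A response of only some classes, podocytes among them, to the isolation of 1 suspension, which could differ between libraries, and a difference by sex or animal were not tested and stay open.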

How the results depend on the processing

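All alternatives named here as added, and the reporter shares, were chosen after seeing the data. Under the alternatives 1987 of 2239 list medians stayed past or within the 2.5% limits as before, 108 fell back within them and 126 passed them, while 18 that had been past a limit changed sign. Of the values of medians within the limits at first 170 changed sign, 24 of them passing a limit. Of 900 gene ratios 758 moved by less than their counting interval, 139 by more and 3 changed sign, and of 118 class shares 84 moved by less. For genes with 0 UMIs in 1 library, which have no such interval, a limit of 1 log2 unit stood in its place. The podocyte stress median lay between 0.33 and 0.79 and above all random lists under each of 18 alternatives, the mesangial interferon median between -0.60 and -0.33 and the glomerular endothelial MHC class I median between -0.48 and -0.26, both past the limit under 18 of 18. In podocytes AY036118 moved by more than its interval under 11 of 16 alternatives (-1.09 to -0.86), Atf3 under 13 (0.46 to 1.17) and Hspa1b under 7 (0.93 to 1.35). Medians that had been past a limit and gene ratios that changed sign, and values of the main classes and groups that left their interval or side, follow, and the others are only counted above, with shares as library labelled female then male; unless said otherwise the cause was not tested. With a mitochondrial limit of 10% podocytes held 51.8% and 51.0%, the parietal metallothionein median turned to -0.23, and the thick ascending limb class, with 16 and 30 cells, gave no value. With a limit of 50% parietal cells held 1.49% and 1.13% and podocytes 69.0% in the library labelled male, and the medians of podocyte transcription factors in glomerular endothelium and of MHC class I in thick ascending limb turned to -0.20 and -0.049. With at least 200 genes parietal cells held 3.50% and 2.54% and podocytes 84.0% and 84.0%; with at least 1000 genes podocytes held 66.0% and 62.4%, and with doublets kept 72.0% in the library labelled male. At resolution 0.5 glomerular endothelium held 3.97% and 3.87%, parietal cells 4.65% and 4.01% and podocytes 67.2% and 65.8%, the arterial class had no cells, podocyte transcription factors turned to -0.10 in glomerular endothelium and -0.14 in parietal cells, parietal metallothionein genes turned to -0.014, and the parietal estrogen and parietal gene medians passed the limit at 0.15 and 0.24. At resolution 2.0 podocytes held 68.7% and 72.1%. With genes scaled within each library podocytes held 71.0% and 72.5%, the interferon median in glomerular endothelium was -0.14, within the limit, and the parietal gene median 0.16, past it. Naming by marker score alone (added) gave 85.5% and 85.0% podocytes, by its construction. Without the 5% of cells with the highest Scrublet scores (added) podocytes held 69.7% in the library labelled male; podocyte transcription factors turned to -1.23 in arterial and -0.95 in glomerular endothelium, Rtn4rl1 in glomerular endothelium to -0.20 and mesangial genes in thick ascending limb to -0.70; the interferon median in arterial endothelium (-0.17), the mesangial gene median in glomerular endothelium (0.071) and the MHC class I median in mesangial cells (-0.17) fell within the limits; retinoid genes in glomerular endothelium (-0.30) and parietal genes (0.15) passed them. With each cell thinned to 3000 UMIs, estrogen genes in glomerular endothelium (-0.024), metallothionein genes in parietal cells (-0.15) and mesangial genes in thick ascending limb (-0.19) changed sign, retinoid genes in glomerular endothelium (-0.42) and parietal genes (0.49) passed the limits, and interferon genes in glomerular endothelium (-0.20) and G2 and M genes in parietal cells (0.25) fell within them. A prior of 50 CPM gave 0.11 for the parietal genes, past the limit. With members at 100 CPM or more, which leaves fewer genes, podocyte transcription factors in glomerular endothelium (-0.46), X-linked partners in thick ascending limb (0.15) and mesangial genes there (-0.15) changed sign, and interferon genes in glomerular endothelium (-0.15) and MHC class I genes in mesangial cells (-0.29) fell within the limits. Podocytes without the cluster led by immediate early genes (added) gave -0.004 for TGF-beta genes. Without cells that carried 2 or more UMIs of a marker of another class, which was Pdgfrb in glomerular endothelium (added; the step removes such transcripts by construction), Pdgfrb (-0.52), Rtn4rl1 (-0.36) and estrogen genes (-0.006) changed sign in glomerular endothelium, as did slit diaphragm genes in mesangial cells (-0.055); the mesangial gene median in glomerular endothelium was 0.04, within the limits, and retinoid genes there (-0.22) and parietal genes in parietal cells (0.26) passed them. Cycling cells were 4.55% and 3.96% at 1 UMI or more, 3.75% and 2.93% without thinning and 0.563% at 3 UMIs or more in the library labelled male. Over all deposited barcodes Y-linked genes were in 81.8% of the library labelled female and Xist in 96.1% of the library labelled male. Of 16 reporter shares 15 were lower after thinning, which removes UMIs. Depth limits the endothelial, parietal and thick ascending limb classes, with 55 to 117 cells per library. No paired analysis was possible because each group has 1 library.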

Other observations

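The gene lists on the circadian clock, glucocorticoids, fasting and interferon-gamma and the reporter analysis in this part were all chosen after the data were seen, and no test of an explanation is reported here. The medians of these gene lists were not computed under any of the alternatives, including those without cells that carried transcripts of another class. How far they depend on the processing is therefore not known.

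Fluorescent reporters of the Confetti cassette were most frequent in parietal epithelial-like cells. At least 1 reporter UMI was found in 59 of 117 of these cells (50.4%; 41.0 to 59.8%) in the library labelled female and in 51 of 75 (68.0%; 56.2 to 78.3%) in the library labelled male, and after thinning to 3000 UMIs in 18.8% (12.2 to 27.1%) and 40.0% (28.9 to 52.0%). In podocyte-like cells the shares were 28.1% and 29.6%, and 8.32% (7.45 to 9.27%) and 10.5% (9.45 to 11.6%) after thinning. Mesangial-like and glomerular endothelial-like cells, which should lack Pax2 activity, had 5.14% and 4.6% at median depths of 8357 and 6932 UMIs, and 1.14% and 1.53% after thinning. Arterial endothelial-like cells, for which the same is expected, had 17.9% (10.4 to 27.7%) and 27.1% (18.0 to 37.8%), and 4.76% (1.31 to 11.7%) and 5.88% (1.94 to 13.2%) after thinning, and the thinned intervals included the podocyte shares of the same library. Thick ascending limb-like cells had 34.5% and 44.6%, and 9.09% and 12.2% after thinning. Podocyte-like cells differed in which reporter they carried: hrGFPIINLS, the nuclear green reporter, was in 15.7% (14.6 to 17.0%) in the library labelled female and 27.4% (25.9 to 28.9%) in the library labelled male, and in 4.26% (3.63 to 4.96%) and 9.63% (8.64 to 10.7%) after thinning. The hrGFPIINLS shares were 10.7% and 24.7% in arterial endothelial-like, 18.2% and 32.4% in thick ascending limb-like, 2.7% and 8.05% in glomerular endothelial-like and 3.77% and 1.15% in mesangial-like cells, with overlapping intervals of both libraries in each of these classes. Whether the difference was particular to podocyte-like cells was not tested. The red reporter tdimer2 was in 2.76% and 4.11% of podocyte-like cells and, after thinning, in 0.791% and 0.900%, which lie within the intervals of mesangial-like and glomerular endothelial-like cells together. Cells with both hrGFPIINLS and tdimer2 were 2.39 (1.69 to 3.28) and 1.68 (1.29 to 2.15) times as many as under independence. EGFP had 0 UMIs in the podocyte-like cells of both libraries. In parietal epithelial-like cells hrGFPIINLS stood at 51.5 against 112 CPM.

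Genes of fatty acid use and fasting were higher in the library labelled female in several classes, with median log2 ratios of 0.67 in podocyte-like, 0.64 in parietal epithelial-like and 0.73 in mesangial-like cells, each above the median of each of 10000 random lists, and of 0.40 in thick ascending limb-like, 0.12 in glomerular endothelial-like and 0.04 in arterial endothelial-like cells. Cpt1a, which encodes the carnitine palmitoyltransferase of the outer mitochondrial membrane, stood at 66.1 against 34.1 CPM in podocyte-like cells. Clock output genes such as Dbp had medians of 0.14 in podocyte-like, 0.29 in parietal epithelial-like, 0.77 in glomerular endothelial-like, 0.31 in mesangial-like, 0.12 in arterial endothelial-like and 0.03 in thick ascending limb-like cells, while clock activator genes, of which 1 to 3 were measured per class, had medians of -0.19, -0.04, -0.72, 0.07, -0.25 and -0.29 in the same order. Arntl, which encodes the clock activator BMAL1, stood at 15.3 against 47.4 CPM in glomerular endothelial-like cells, the class with the lowest of these medians. Glucocorticoid response genes had medians of 0.22 in podocyte-like, 0.33 in parietal epithelial-like, 0.44 in glomerular endothelial-like, 0.21 in arterial endothelial-like and -0.01 in mesangial-like cells. In thick ascending limb-like cells their median was 0.14 (percentile 91.4), within the limits of the random lists. Genes induced by interferon-gamma were lower in the library labelled female in arterial endothelial-like (-0.78), mesangial-like (-0.73), glomerular endothelial-like (-0.37) and parietal epithelial-like cells (-0.20), while the 3 measured ones in thick ascending limb-like cells had a median of 1.07 and the 2 in podocyte-like cells, with ratios on both sides of 1, a median of 0.30. The times of day at which the mice were killed are not given in the sources used here.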
